A study of Mus musculus with 12 samples.

How the data were processed

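Total RNA from mouse cerebellum was measured on 12 Affymetrix whole-transcript arrays, 1 array per mouse. The extraction protocol describes separate animals, 6 lacking Ciz1 and 6 controls, with 3 males and 3 females of each. Groups were taken from the source names, which give genotype and sex, and are called WT_male, WT_female, KO_male and KO_female here, with 3 arrays each. Replicate numbers follow the order of the sample records and only name an array. The labels disagree in places: the genotype field of the controls reads Ciz1+/-, while their source name calls them wild type and the extraction protocol gives Ciz1+/+. The protocol gives an age of 10 months and the series design a range of 6 to 10 months. The labels do not say how the Ciz1 allele was made, so which part of the gene the array's probes cover relative to the change was not known here.

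The deposited values are RMA expression values at the core-exon level from Affymetrix Expression Console, per the labels. Transcriptome Analysis Console 3.0 is also named, per the submitters' processing notes. The authors deposited each value as an intensity on a linear scale, with array medians between 96.5 and 98.7. The design fixed in advance had assumed log2 values, so log2 of each deposited intensity was taken here before any test, with no pseudocount and no further normalization. The authors' own statistical test and the genome build of the array annotation are not given in the sources used here.

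The value table had 41345 rows. GEO's platform annotation paired 23521 rows with 1 gene symbol, 1814 rows with several and 16010 rows with none. Rows with exactly 1 symbol were kept, and for the 1082 genes with several such rows the row with the highest mean over the 12 arrays was used, which gave 22180 genes. Of these, 21994 matched a RefSeq gene table of assembly GRCm38.p6 by gene ID. That table was used for chromosome assignment and for which genes neighbour each other, and no coordinates are printed because the array's build is not known. No genes were removed for low brightness.

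Tests used limma 3.58.1 in R 4.3.3. A mean was fitted for each of the 4 groups, with a spread shared over all 12 arrays, and moderated with eBayes. The contrasts were knockout against wild type averaged over the sexes, knockout against wild type within males and within females, the difference between those effects (females minus males), and females against males averaged over genotype. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 22180 genes, with a threshold of 0.05. Differences are knockout minus wild type, or females minus males, on the log2 scale. Every adjusted p of a gene in the text comes from limma.

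The genes named were set by a rule written before the data were examined. Ciz1 came first. For the contrast over both sexes the rule took up to 10 genes in each direction past the threshold, and for males, females and sex up to 5. For the interaction it took up to 10 genes past the threshold, those with the smallest p. Where fewer passed, genes with the smallest unadjusted p were added up to 5 per direction. Symbols of predicted, Riken, olfactory, vomeronasal and small RNA genes were counted but not named by rank. The 3 members of each gene list with the smallest p and the sex-linked genes Xist, Ddx3y, Eif2s3y, Kdm5d and Uty were added. Ddx3y had no row with its name alone and was not analysed here. The gene 1110008P14Rik falls outside the rule and was named after its values were seen, as were the genes beside Ciz1. Further members of the lists were named as examples after their values were seen.

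Gene lists were also fixed before the data were examined: 25 lists with 558 entries, of which 66 did not match a tested gene. They cover cell cycle, p53 targets, inherited dystonia and ataxia, the cell types of the cerebellum and its surroundings, immediate early genes and clock genes. They also cover interferon response, heat shock and ER stress, oxidative phosphorylation, ribosomal proteins and synaptic transmission. The rest are Xist partners and X-inactivation factors, and genes that escape X inactivation or lie on the Y chromosome. Each list, and the set of 899 X-linked genes, was tested with camera and its preset correlation of 0.01, adjusted over all lists within a contrast. This preset treats the members of a list as almost independent, so each call is given with the adjusted p obtained with an estimated correlation. None of the calls of a list held with an estimated correlation. The fry test of limma, which asks whether the members move one way on balance, was an alternative. Genes within 10 Mb of Ciz1 were compared with the rest by Fisher's exact test.

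The main test was tried on simulated data with the real means and moderated spreads of 22180 genes. In each simulation 200 genes were changed, and noise was drawn independently for each gene. In the contrast over both sexes the main test recovered 54% of genes changed by 0.3, 90% at 0.5 and 98% at 0.8 on the log2 scale. For females alone these shares were 18%, 58% and 96%, and for the interaction 2%, 28% and 76%. With 200 genes changed the adjusted threshold is easier to pass than in the real data, where few genes passed. These shares may therefore overstate the recovery in the real data. The median standard error of a gene was 0.06 over both sexes and 0.09 in 1 sex. The number of arrays limits the precision. Pairs of arrays correlated between 0.992 and 0.995 and no pair was identical.

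Alternatives covered the model without sex, trended, robust and no moderation, array weights, further scaling, all rows of the table, averaged rows, filters on dim genes, other thresholds, each array left out in turn, and the other list tests. No labels give a hybridisation or scan batch, so no batch was tested.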

Results

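Gene expression was compared between the cerebellum of mice lacking Ciz1 and of wild-type mice, in both sexes, with 3 mice in each of the 4 groups of sex and genotype. Ciz1 encodes a nuclear protein that takes part in the start of DNA replication and helps to hold Xist RNA on the inactive X chromosome. Log2 differences between arrays of one group had an SD of 0.193 to 0.214 across genes. On the first principal component, with 16% of the variance, the 3 KO_female arrays stood apart, at 10.72 to 16.01 against -12.18 to 3.54 in the other 9. The median difference over all genes between knockout and wild type was -0.0045 in males and 0.0016 in females on the log2 scale.

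Ciz1 was lower in every knockout array than in every wild-type array. Its level was 8.76 ± 0.08 (SD, n = 6) in wild type and 7.13 ± 0.18 (SD, n = 6) in knockout on the log2 scale, a difference of -1.64 (SE 0.07; limma adjusted p = 1.42e-06) or 3.11-fold. The difference was -1.67 in males (adjusted p = 5.81e-05) and -1.61 in females (adjusted p = 8.7e-05). The Ciz1 row kept a signal in the knockout, and the place of its probes relative to the altered part of the gene was not known.

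**Figure D1:**
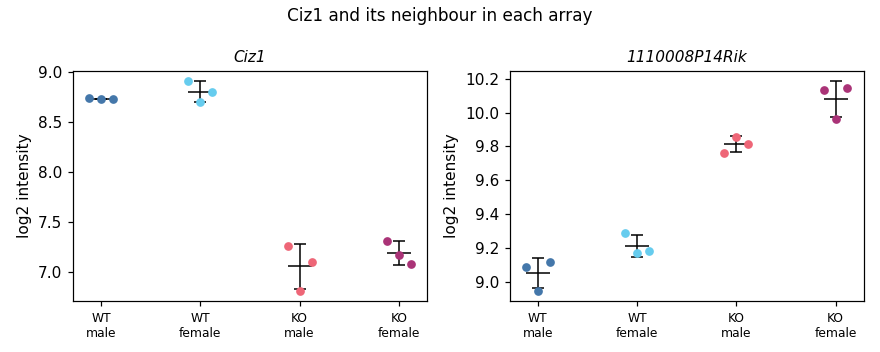
Log2 intensity of Ciz1 and of 1110008P14Rik in each of the 12 arrays, by group, with points for arrays and black marks for the group mean ± SD (n = 3); the vertical axes do not start at 0. Ciz1 lay between 6.82 and 7.31 in the knockout arrays and between 8.70 and 8.90 in the wild-type arrays, while 1110008P14Rik lay higher in all 6 knockout arrays.

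The gene beside Ciz1 in the chromosome order, 1110008P14Rik, rose in the knockout by 0.82 (SE 0.05; adjusted p = 2.69e-05), with like differences in males (0.76) and females (0.87). This gene was singled out after its values were seen. The next genes on that side, Lcn2, which encodes the iron-binding secreted protein lipocalin 2, and Ptges2, a prostaglandin E synthase, differed by 0.37 (SE 0.16; adjusted p = 0.517) and 0.25 (SE 0.05; adjusted p = 0.229) and did not pass the test. On the other side Dnm1, which encodes the endocytic GTPase dynamin 1, differed by 0.04 (SE 0.04), and Pomt1 by 0.17 (SE 0.06; adjusted p = 0.467). Of the 329 tested genes within 10 Mb of Ciz1, 1 was past the threshold, against 3 of 21664 elsewhere, an odds ratio of 22 (95% interval 0.418 to 274.5; Fisher's exact test, two-sided p = 0.0585). With 1 gene called there, the test does not settle whether the shares differ. At an unadjusted p under 0.01 the counts were 9 of 329 genes there and 492 of 21664 elsewhere. The odds ratio was then 1.21 (95% interval 0.545 to 2.346, Fisher's exact test, two-sided p = 0.5728).

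**Figure D2:**
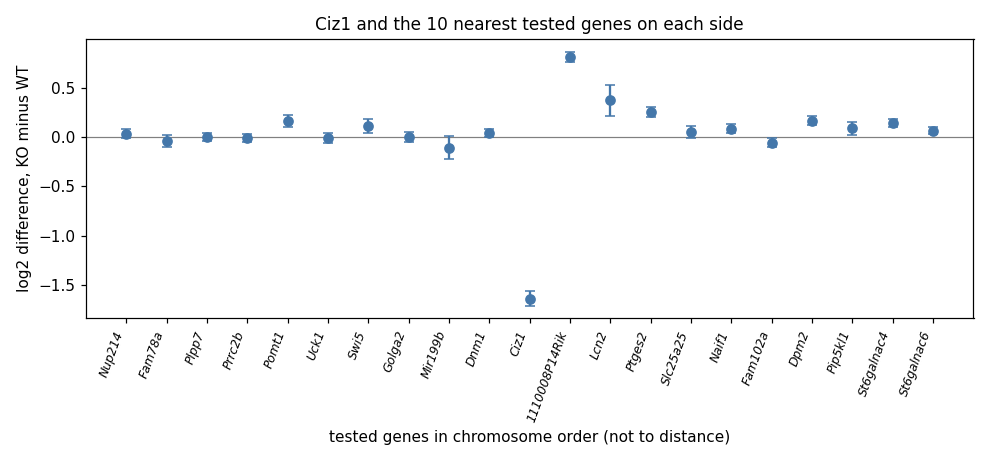
Log2 difference, knockout minus wild type over both sexes, of Ciz1 and the 10 nearest tested genes on each side in chromosome order; bars are standard errors, and spacing does not show distance. Ciz1 stood at -1.64, 1110008P14Rik at 0.82 and Lcn2 at 0.37, while on the other side Dnm1 stood at 0.04 and Pomt1 at 0.17.

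Across both sexes, 5 of 22180 genes passed the test for genotype, 2 higher and 3 lower in the knockout. Besides Ciz1 and 1110008P14Rik these were Ces3b, a carboxylesterase, with a difference of 0.52 (SE 0.06; adjusted p = 0.00798), Opalin, a membrane protein of oligodendrocytes, which fell by 0.45 (SE 0.06; adjusted p = 0.037), and Hrk, a BH3-only protein that promotes cell death, which fell by 0.37 (SE 0.04; adjusted p = 0.0166). Ces3b was a dim gene, with a mean brightness in the lowest 6.6% of genes, and was not shown to lie above background in any group, so its difference is not read as a change in its RNA. It was 0.15 in males and 0.90 in females. The group that stood apart was WT_female, at 3.62 on average against 4.34 over the other 9 arrays. The fall of Opalin was larger in females, at -0.72, but the sexes were not shown to differ in it (limma adjusted p for the interaction = 0.772). Opalin stood at 6.74 to 6.90 in KO_female and 7.33 to 7.52 in KO_male, against 7.44 to 7.71 in the wild-type arrays. The genes next in rank did not pass: Mpp4 differed by 0.32, Ascl4 by 0.35, Creld2 by 0.30 and Gng3 by 0.30, with adjusted p from 0.141 to 0.154. Apold1 differed by -0.29 (adjusted p = 0.124) and Sprr3, also dim, by -0.29 (adjusted p = 0.141). Of these, Mpp4, Creld2, Gng3 and Apold1 passed with an intensity trend (adjusted p = 0.0189, 0.0189, 0.0156 and 0.0376) and over genes above the median brightness (0.0216, 0.0239, 0.0283 and 0.0165). At an unadjusted p under 0.05 there were 2053 genes, 972 higher and 1081 lower, where a share of 0.05 of the genes would be 1109. Genes can move together across arrays, and how far this count varies by chance was not tested. Without WT_female replicate 1 Gng3 passed (adjusted p = 0.0448), and without WT_male replicate 1 Mal did (0.0309). The call of Opalin was kept only without WT_female replicate 1, WT_female replicate 3 or KO_male replicate 1, and was lost without any other array (adjusted p up to 0.158). The call of Hrk was lost without WT_male replicate 2 or 3, WT_female replicate 2, KO_male replicate 3 or any of the 3 KO_female arrays (adjusted p up to 0.0854). With the choroid plexus level of each array as a covariate, added after seeing the data, Opalin (-0.47, SE 0.06; adjusted p = 0.0723) and Hrk (-0.37, SE 0.05; adjusted p = 0.0716) no longer passed.

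Markers of oligodendrocytes, the myelin-forming cells, fell as a list in the knockout. Their median difference was -0.20, 17 of 20 members were lower, and 12 were past the threshold when adjusted over the list alone, against 1, Opalin, over all genes. Among these 12 were the myelin proteins Mal (-0.36, SE 0.06), Cldn11 (-0.28, SE 0.07), Mog (-0.35, SE 0.09) and Mbp (-0.21, SE 0.07), and the transcription factor Sox10 (-0.22, SE 0.08). The precursor markers Pdgfra (0.01), Cspg4 (0.11) and Gpr17 (0.01) did not pass. By sex the median was -0.12 in males, with 0 members past the threshold over the list alone, and -0.27 in females, with 9. The list test gave an adjusted p of 2.67e-11 with the preset correlation, and the call was lost with adjusted p = 0.408 with an estimated correlation.

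Immediate early genes, which neurons transcribe within minutes of activity, fell as a list. The median difference was -0.12, 24 of 29 members were lower, and 8 were past the threshold when adjusted over the list alone, 7 lower and 1 higher, against 0 over all genes. Nr4a2 differed by -0.68 (SE 0.13), Nr4a1 by -0.44 (SE 0.14), Dusp1 by -0.32 (SE 0.08) and Fosb by -0.33 (SE 0.10), while Dusp6 was the member that was higher, by 0.14 (SE 0.05). Arc, whose RNA is carried to synapses, differed by -0.01 (SE 0.05). The list test gave an adjusted p of 6.54e-06, lost with adjusted p = 0.408 with an estimated correlation.

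Heat shock and endoplasmic reticulum (ER) stress genes rose as a list, with a median difference of 0.09 and 18 of 27 members higher. When adjusted over the list alone 9 were past the threshold, 8 higher and 1 lower, against 0 over all genes. Among the 8 were the ER proteins Sdf2l1 (0.43, SE 0.08), Creld2 (0.30, SE 0.05), Pdia6 (0.23, SE 0.04), the chaperone Hspa5 (0.22, SE 0.05) and Manf (0.23, SE 0.05). The cytosolic heat shock proteins Hspa8 (-0.01), Hsp90aa1 (-0.07) and Hspa1a (-0.12) did not pass. In males alone the list did not pass (median -0.01, 13 members higher and 14 lower, adjusted p = 0.922), and Sdf2l1 differed by 0.01 there. The list test gave an adjusted p of 6.54e-06, lost with adjusted p = 0.408 with an estimated correlation.

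Markers of Bergmann glia and astrocytes fell as a list (median -0.05, adjusted p = 0.0053), with 0 members past the threshold when adjusted over the list alone and 0 over all genes, and the call was lost with adjusted p = 0.408 with an estimated correlation. Vim differed by -0.13, Aqp4 by -0.17 and Slc1a2 by -0.10. Microglia markers rose as a list (median 0.05, adjusted p = 0.0265), lost with adjusted p = 0.812 with an estimated correlation; Cd68, a lysosomal protein of phagocytes, was the 1 member past the threshold when adjusted over the list alone (0.27, SE 0.06), against 0 over all genes. Fcrls differed by 0.20 and C1qb by 0.17. The microglia call was lost without WT_male replicate 2 (adjusted p = 0.0873), WT_female replicate 3 (0.259), KO_male replicate 2 (0.171), KO_male replicate 3 (0.0521), KO_female replicate 1 (0.127) or KO_female replicate 2 (0.0683), and over genes above the median brightness (0.0505).

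Choroid plexus, the secretory tissue of the ventricles next to the cerebellum, varied between arrays in every group. Ttr, its most abundant transcript, ranged from 7.59 to 13.1 on the log2 scale within KO_female and from 8.88 to 13.3 within WT_female. All 19 choroid plexus markers were lower on average in the knockout (median -0.25, adjusted p = 0.000577), with 0 past the threshold when adjusted over the list alone and 0 over all genes, and the call was lost with adjusted p = 0.812 with an estimated correlation. Slco1a5 differed by -0.26, Folr1 by -0.36 and Otx2 by -0.28. The call was also lost without WT_male replicate 1 (adjusted p = 0.239) or WT_female replicate 2 (adjusted p = 0.0734), and over genes above the median brightness (0.14).

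Markers of the main neurons of the cerebellum did not pass as lists: Purkinje cells had a median difference of 0.02 (adjusted p = 0.719), granule cells 0.02 (adjusted p = 0.574) and inhibitory interneurons -0.00 (adjusted p = 0.905). Ppp1r17 differed by 0.11, Lhx1 by -0.09, Rgs8 by 0.06, Etv1 by 0.15, Calb2 by 0.10, Gabrd by 0.07, Slc6a5 by -0.09, Ptprk by 0.09 and Gad2 by -0.07. Vascular and meningeal markers (adjusted p = 0.847), brainstem and monoaminergic markers (0.905), blood markers (0.431), clock genes (0.923), ribosomal proteins (0.905), synaptic transmission (0.872) and interferon response (0.0666) did not pass either. The interferon list passed without WT_male replicate 1 (adjusted p = 0.013), WT_female replicate 2 (0.0126), KO_male replicate 1 (0.0137) or KO_female replicate 3 (0.00408). Oxidative phosphorylation as a list did not pass (adjusted p = 0.699); within it Ndufs4, a subunit of complex I, was past the threshold when adjusted over the list alone (0.28, SE 0.05), as were Rps27 (0.33, SE 0.08) and Rps19 (-0.19, SE 0.05) within the ribosomal proteins, and none of these 3 passed over all genes. Ndufs4 passed with an intensity trend (adjusted p = 0.0189) and over genes above the median brightness (0.0331).

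The known roles of Ciz1 in DNA replication and X inactivation made cell cycle and X-linked genes of interest. Genes of G1/S and DNA replication (median 0.02, adjusted p = 0.627), of G2/M and mitosis (median 0.01, adjusted p = 0.942) and p53 targets (median -0.02, adjusted p = 0.627) did not pass, with 0 members past the threshold when adjusted over each list alone. The cell cycle inhibitor Cdkn1a differed by 0.31 (SE 0.12), Mcm2 by 0.09, Ccnd1 by 0.12, Bub1b by -0.31, Tpx2 by -0.18, Ube2c by 0.26, Phlda3 by -0.21 and Btg2 by -0.17. The inherited dystonia list, which includes Prrt2 (0.10), Vps16 (-0.07) and Prkra (-0.07), had an adjusted p of 0.905, and the inherited ataxia list, with Pdyn (-0.16), Ppp2r2b (-0.10) and Elovl5 (0.08), one of 0.7. The list of Xist partners and X-inactivation factors, among them Hnrnpu (-0.14), Ftx (0.15) and Rlim (-0.10), did not pass (adjusted p = 0.808). Y-linked genes did not pass either (adjusted p = 0.872). Nor did genes that escape X inactivation (adjusted p = 0.872), whose median was -0.03 while the test pointed up. The 899 X-linked genes had median differences of -0.01 in females (adjusted p = 0.854) and -0.01 in males (adjusted p = 0.922), and the sexes did not differ (adjusted p = 0.92).

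Within males, 5 genes passed the test for genotype, 2 higher and 3 lower. Nnt, the mitochondrial enzyme that makes NADPH from NADH, rose by 0.54 (SE 0.06; adjusted p = 0.0071), with 8.02 ± 0.06 (SD, n = 3) in KO_male and between 7.38 and 7.53 on average in the other groups. Rhoj, a small GTPase of endothelial cells, fell by 1.30 (SE 0.15; adjusted p = 0.00999), and Apold1, another endothelial gene, fell by 0.48 (SE 0.06; adjusted p = 0.0359); the others were Ciz1 and 1110008P14Rik. The genes next in rank, Gbp9 (0.34), Slfn2 (0.55), Mpp4 (0.33), Tdo2 (-0.37), Nat8f2 (-0.45) and the dim gene Speer3, not shown to lie above background, did not pass, with adjusted p from 0.379 to 0.57. At an unadjusted p under 0.05 there were 1202 genes, near the 1109 that a share of 0.05 of the genes would be. Without WT_male replicate 1 the call of Nnt was lost (adjusted p = 0.0712), as it was without WT_male replicate 3 (0.0607) or KO_male replicate 2 (0.0644), and that of Rhoj was lost without any WT_male array or without KO_male replicate 2 or 3 (adjusted p up to 0.0937). The call of Apold1 was lost without any of the 12 arrays (adjusted p from 0.0645 to 0.24) and with the choroid plexus covariate (-0.48, SE 0.07; adjusted p = 0.107).

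In males, interferon response genes rose as a list: all 17 members were higher, with a median difference of 0.18 and an adjusted p of 2.73e-06, while 0 members passed adjusted over the list alone or over all genes, and the call was lost with adjusted p = 0.284 with an estimated correlation. Ifit1 differed by 0.68, Oasl2 by 0.72 and Usp18 by 0.48. Immediate early genes fell (median -0.15, adjusted p = 4.78e-06; adjusted p = 0.331 with an estimated correlation), as did oligodendrocyte markers (median -0.12, adjusted p = 0.000845; adjusted p = 0.623 with an estimated correlation) and choroid plexus markers (median -0.31, adjusted p = 0.00266; adjusted p = 0.885 with an estimated correlation), each with 0 members past the threshold when adjusted over the list alone. The oligodendrocyte call was lost without KO_male replicate 2 (adjusted p = 0.326). Microglia markers rose (median 0.09, adjusted p = 0.00241; adjusted p = 0.534 with an estimated correlation), a call lost without KO_male replicate 2 (adjusted p = 0.0755). The blood markers, a list of 2 genes, passed (adjusted p = 0.0385; adjusted p = 0.284 with an estimated correlation). The dim gene S100a8 differed by 0.32, past the threshold when adjusted over the list alone, and S100a9 differed by 0.16 and did not pass. Bergmann glia and astrocyte markers fell by the test (adjusted p = 0.0456; adjusted p = 0.475 with an estimated correlation) although their median was 0.00; Vim (-0.23) and Fabp7 (-0.40) were the 2 members past the threshold when adjusted over the list alone. Genes that escape X inactivation fell (median -0.13, adjusted p = 0.0202, and adjusted p = 0.284 with an estimated correlation). All 9 members were lower, with 0 past the threshold when adjusted over the list alone and 0 over all genes. The call of the escape list was lost without WT_male replicate 3 (adjusted p = 0.476), KO_male replicate 2 (0.0602) or KO_male replicate 3 (0.0796). The astrocyte call was kept only without WT_male replicate 1, KO_male replicate 2, KO_female replicate 2 or KO_female replicate 3 (adjusted p up to 0.586 without another array) and was lost over genes above the median brightness (0.068). The blood call was lost without WT_male replicate 2, KO_female replicate 1 or any KO_male array (adjusted p up to 0.261). The choroid plexus call was lost without WT_male replicate 1 (adjusted p = 0.92), where its direction also turned. It was lost too without KO_male replicate 1 (0.154) or KO_male replicate 3 (0.0927), and over genes above the median brightness (0.157). Lists that passed in males only with an array left out were Purkinje cells (0.0044) and granule cells (0.00217) without KO_male replicate 2, and granule cells (0.0394) and inhibitory interneurons (0.047) without WT_male replicate 2.

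Within females, 5 genes passed, 3 higher and 2 lower. Sdf2l1, an ER protein, rose by 0.85 (SE 0.11; adjusted p = 0.0321), while Opalin fell by 0.72 (SE 0.08; adjusted p = 0.0144); the others were Ciz1, 1110008P14Rik and the dim gene Ces3b, with a difference of 0.90 (SE 0.08; adjusted p = 0.00105). Next in rank and not past the threshold were Hspa5 (0.47), Creld2 (0.47), Trim69 (0.53), Hrk (-0.41), Gpr45 (-0.44) and Trank1 (-0.81), with adjusted p from 0.0626 to 0.085. At an unadjusted p under 0.05 there were 1884 genes. Hspa5, Creld2 and Trank1 passed with an intensity trend (adjusted p = 0.00522, 0.00683 and 0.00522) and over genes above the median brightness (0.00587, 0.0104 and 0.0145). Above a log2 mean of 5 Hspa5 (0.0396), Creld2, Trim69, Hrk and Gpr45 (0.048 each) passed, and without KO_female replicate 2 Trank1 did (0.0427). The call of Opalin in females was lost without WT_female replicate 1 or 2 or KO_female replicate 1 or 3 (adjusted p up to 0.0998). The call of Sdf2l1 was lost without WT_male replicate 3, KO_male replicate 2 or any WT_female or KO_female array (adjusted p up to 0.184), and with the choroid plexus covariate (0.81, SE 0.11; adjusted p = 0.0648).

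**Figure D3:**
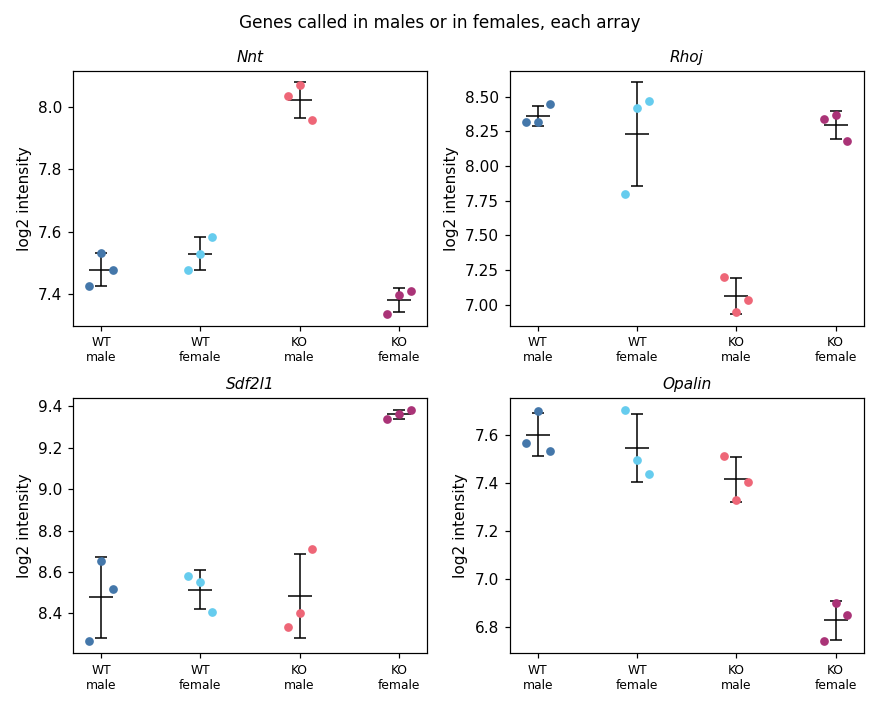
Log2 intensity of Nnt, Rhoj, Sdf2l1 and Opalin in each of the 12 arrays, by group, with points for arrays and black marks for the group mean ± SD (n = 3); the vertical axes do not start at 0. Nnt stood at 8.02 and Rhoj at 7.06 in KO_male, and Sdf2l1 at 9.36 and Opalin at 6.83 in KO_female, apart from the other groups.

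In females, heat shock and ER stress genes rose as a list, with a median difference of 0.19, 21 of 27 members higher and an adjusted p of 1.86e-11, lost with adjusted p = 0.304 with an estimated correlation. When adjusted over the list alone 8 members were past the threshold, against 1, Sdf2l1, over all genes. Among them were Hspa5, Manf (0.41), Pdia6 (0.37), Xbp1 (0.34), a transcription factor of the unfolded protein response, and Calr (0.22). Oligodendrocyte markers fell, with 18 of 20 members lower, a median of -0.27 and an adjusted p of 1.86e-11, lost with adjusted p = 0.304 with an estimated correlation; 9 members were past the threshold when adjusted over the list alone, among them Mal (-0.53), Mog (-0.45) and Mobp (-0.38), against 1 over all genes. The 3 KO_female arrays on which both lists rest also stood apart over all genes, at 10.72 to 16.01 on the first principal component against -12.18 to 3.54 in the other 9. Genes that escape X inactivation rose (median 0.10, adjusted p = 0.0389, and adjusted p = 0.304 with an estimated correlation), with 7 of 9 members higher and 2 lower. Kdm5c (0.28), Pbdc1 (0.25) and Utp14a (0.31) were past the threshold when adjusted over the list alone. Kdm6a was among the lower, at 10.10 to 10.20 in KO_female against 10.19 to 10.28 in WT_female. The call of the escape list was lost without WT_female replicate 3 (adjusted p = 0.0878), KO_male replicate 1 (0.0554), KO_female replicate 1 (0.101) or KO_female replicate 2 (0.0862). Choroid plexus markers (median -0.21, adjusted p = 0.0447) and immediate early genes (median -0.05, adjusted p = 0.0327) fell too, both lost with adjusted p = 0.847 with an estimated correlation; Nr4a2 (-0.81) was the 1 immediate early gene past the threshold when adjusted over the list alone. The choroid plexus call was lost without WT_female replicate 2 or 3, KO_male replicate 1 or 3, or KO_female replicate 1 or 3 (adjusted p up to 0.937) and over genes above the median brightness (0.415). That of the immediate early genes was lost without WT_female replicate 2 (0.406), KO_female replicate 1 (0.0719) or KO_female replicate 3 (0.198). By fry 3 of these lists passed in females: heat shock and ER stress, oligodendrocyte markers and the escape genes. Lists that passed in females only with an array left out were interferon response without KO_female replicate 1 (0.0133), oxidative phosphorylation without KO_female replicate 2 (0.0177), inhibitory interneurons without WT_female replicate 1 (0.0327) and vascular and meningeal markers without KO_female replicate 3 (0.042). Bergmann glia and astrocytes passed without KO_male replicate 2 (0.0348), without KO_female replicate 3 (0.042) and over genes above the median brightness (0.0417).

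**Figure D4:**
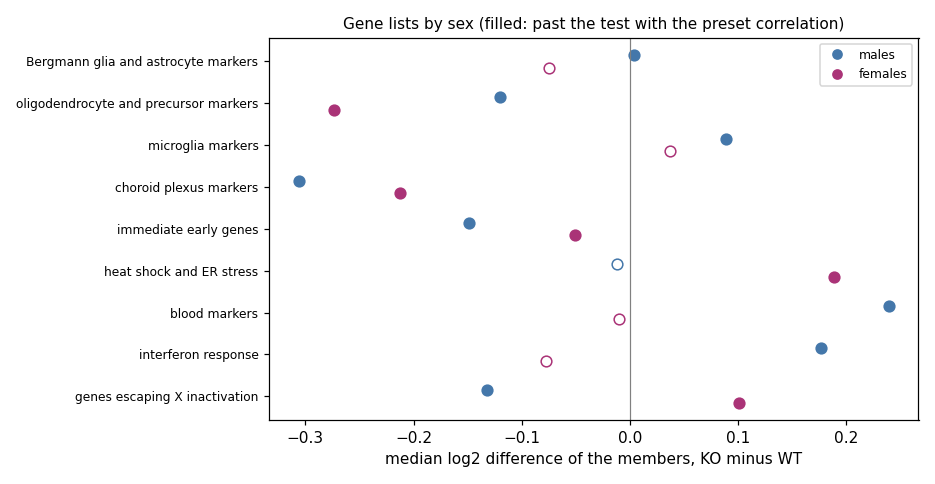
Median log2 difference, knockout minus wild type, of the members of each gene list that passed the list test in any contrast, in males (blue) and females (purple); filled points passed with the preset correlation and open points did not. Heat shock and ER stress genes stood at 0.19 in females and -0.01 in males, and interferon response genes at 0.18 in males and -0.08 in females.

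Whether the effect of genotype differed between the sexes was tested directly, and limma called 0 genes, with 1070 at an unadjusted p under 0.05. Nnt came nearest, with a difference between the effects of -0.69 (SE 0.08; adjusted p = 0.0625), followed by Ces3b (0.75, SE 0.11; adjusted p = 0.243) and Rhoj (1.37, SE 0.21; adjusted p = 0.243). The other genes named were the dim gene Ly6i (0.55), Sdf2l1 (0.84), Hspa5 (0.50), Rtp2 (-0.55), Trank1 (-0.84), Tpbg (-0.48) and Opalin (-0.53). These 10 were the 5 with the smallest p in each direction among symbols named by rank, not the first 10 over all genes. With all 22180 genes and no intensity trend, the genes called in 1 sex were not shown to differ between the sexes. Nnt passed with an intensity trend (adjusted p = 0.0148), over genes above the median brightness (0.00355) and over genes above a log2 mean of 5 (0.0317). Rhoj passed with a trend (0.0148), over genes above the median brightness (0.0311) and without WT_female replicate 1 (0.0361), in which it was at 7.80.

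The sexes themselves differed as their labels give. Xist, the RNA that coats the inactive X chromosome, was higher in females by 5.51 (SE 0.39; adjusted p = 7.09e-05), and the Y-linked genes Eif2s3y, Kdm5d and Uty were lower, with differences of -4.70, -4.34 and -3.95. Females carry no Y chromosome, so their values in these rows, from 4.18 to 5.20 on average by group, are background and the differences are lower bounds in size. The male values of Xist were not shown to lie above background either, so the size of its difference is not read as exact. In all 8 genes passed, 3 higher and 5 lower in females: the X-linked genes Kdm5c (0.46, adjusted p = 0.000473) and Kdm6a (0.46, adjusted p = 0.000663) were higher, and AA536875 (-0.47) and Nnt (-0.29) were lower, both with an adjusted p of 0.0384. For Nnt the difference came from KO_male, at 8.02, since wild-type females (7.53) were not lower than wild-type males (7.48). Pbdc1 (0.30, adjusted p = 0.112) and Pla1a (0.27, adjusted p = 0.162) did not pass. Pbdc1 passed with an intensity trend (0.0229) and over genes above the median brightness (0.0157). Xist stood at 8.71 in WT_male replicate 3, against 5.75 to 6.67 in the other 5 males and 12.1 on average in females. The call of Nnt by sex was lost without any of the 12 arrays (adjusted p from 0.0558 to 0.179). It was lost too with the choroid plexus covariate, where the difference stayed alike (-0.295, SE 0.0428, adjusted p = 0.0697). That of AA536875 was lost without any array other than WT_male replicate 1 and KO_female replicate 1 (adjusted p up to 0.165).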

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

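The tests on the DNA around Ciz1, on female RNA in WT_male replicate 3, on splits without Ciz1 and its neighbour, and on genes of like brightness were chosen after the result was seen.

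The list tests for a difference between the sexes in the effect of genotype passed for 4 lists. Heat shock and ER stress genes differed with an adjusted p of 4.19e-10 (median difference between the effects 0.17; adjusted p = 0.248 with an estimated correlation). Interferon response genes differed with an adjusted p of 4.62e-06 (median -0.26; adjusted p = 0.316 with an estimated correlation). Genes that escape X inactivation differed with an adjusted p of 0.000144 (median 0.22; adjusted p = 0.107 with an estimated correlation), and by fry with 0.0253. Oligodendrocyte markers differed with an adjusted p of 0.000645 (median -0.15; adjusted p = 0.874 with an estimated correlation), a call lost without KO_male replicate 1 (adjusted p = 0.146). Lists that passed for this difference only with an array left out included Purkinje cells (0.000386), granule cells (0.0331), inhibitory interneurons (0.0153) and vascular and meningeal markers (0.0401) without KO_male replicate 2, microglia without WT_female replicate 3 (0.0195) or KO_male replicate 1 (0.02), immediate early genes without WT_female replicate 2 (0.0475) and oxidative phosphorylation without KO_female replicate 2 (0.0209). Inhibitory interneurons passed also without WT_male replicate 2 (0.0168), WT_female replicate 1 (0.0106) or KO_female replicate 2 (0.047).

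Rows with no single gene name were outside the comparisons, and 3 of them passed the threshold for genotype when all rows of the table were tested, all higher in the knockout, by 0.79 to 1.84. For sex 5 rows without any name passed, 4 higher and 1 lower in females.

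Beside Ciz1, 1110008P14Rik was higher in the knockout, by 0.8172. Of the 9 tested genes after it 8 were higher on average and 0 passed the test, with a mean difference of 0.13, at the percentile 99.71 of 21804 windows of 9 adjacent genes; the 9 genes on the other side had a mean of 0.02, at the percentile 70.4, and the sides were not tested against each other. Probes of 1110008P14Rik that take Ciz1 RNA would have fallen with Ciz1, while the row rose. That rise is the pattern itself, seen beforehand, so it is no separate test of this explanation. Flanking DNA of another strain reaching 10 Mb could raise the share of genes with a small p there. Beyond the 10 nearest genes on each side 19 of 309 genes had an unadjusted p under 0.05 against 2017 of 21634 elsewhere. The odds ratio was 0.637 (95% interval 0.377 to 1.02), so the share was not shown to be raised. Flanking DNA that changes only a few genes need not raise it, so this share cannot exclude such DNA. An effect of the altered locus on its neighbours is left open, since the side and its genes had been seen before the windows were ranked. Flanking DNA is left open too, both a shorter stretch, which was not tested, and a longer one that changes few genes.

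Some genes stood apart in all 3 arrays of a single group. By a gap of at least 0.3 log2 to each of the other 9 arrays, KO_female had 6 such genes, among them Sdf2l1, Opalin, Manf and Trank1, KO_male had 2, Nnt and Rhoj, and each wild-type group had 1, Zbtb16 in WT_male and the dim gene Ces3b in WT_female. For KO_female 0 of 100 random sets of 3 arrays that mix groups had as many and the highest had 2, which argues against a chance choice of 3 arrays there, while 2 of 100 had as many as KO_male and 18 of 100 as many as either wild-type group. In the deposited values no shift shared by genes of like brightness was as large as the differences of these genes. The 500 genes nearest in brightness to each of these 10 genes shifted by at most 0.0367 in the median, where the genes themselves shifted by at least 0.45. Under quantile normalization and median centring the gaps stayed at 0.305 or more (0.3508 for Nnt in KO_male). Neither these shifts nor these gaps test scaling as a cause, since RMA had already scaled the arrays and keeps such shared shifts small. The array medians lay within 0.0341 of each other. Sequence variants that differ between the families of the animals cannot be told apart from an effect of genotype and sex: the 6 genes nearest Nnt differed by a median of 0.067 in males, but a value per gene does not show whether the probes within it move together, and the labels give no litters.

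With the mean intensity of the other 5 males subtracted from both, Xist in WT_male replicate 3 reached 7.93% of the female level. Female RNA in this sample at that share would lower the Y-linked rows by 0.12. The mean of the 3 rows lay at -0.1599 from the other 5 males, whose SD was 0.07. The rows were not alike. Eif2s3y stood at 8.963 against a mean of 8.992 (SD 0.139) in the other 5 males. Kdm5d stood at 8.557 against 8.821 (SD 0.077) and Uty at 8.883 against 9.07 (SD 0.071). The row shared by Xist and Tsix could not decide, since the share would raise it by 0.03 against a range of 0.51 over the other 5 males; it lay at -0.1196 from the highest of them. Female RNA and array noise in one row therefore cannot be told apart, and no biological explanation was tested.

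Other splits of the arrays were used to ask whether chance could give as many calls. For genotype, 1 of 100 splits with 3 mice of each sex per side, the real one, called as many as 5 genes, and the highest of the others called 3. The 5 include Ciz1, which defines the split, and its neighbour 1110008P14Rik; without them the real split called 3, the highest other 3, and 2 of 100 splits, the real one included, were as large. The lead of the real split for the count of 5 thus rests on Ciz1 and its neighbour. Without them another split did as well, so the splits cannot exclude chance for the other 3 genes called. For sex, 1 of 100 splits, the real one, called as many as 8 and the highest other 3. The 8 include the Y-linked Eif2s3y, Kdm5d and Uty, and Xist, Kdm5c and Kdm6a from the X chromosome. Those genes follow the sex that defines the split. The lead of the real split therefore says nothing about chance for AA536875 and Nnt. For males and for females the 6 arrays make 10 splits, too few for a share under 0.05; the real split called 5 genes in each, the highest other 0, and 1 split was as large. For the interaction the real count was 0, which all 100 splits reach, the highest with 3, so the splits say nothing about chance.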

How the results depend on the processing

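The choroid plexus covariate and the escape list without Xist were chosen after seeing the data. No paired analysis was possible because the labels give no replicate numbers shared between groups. Over 2786 alternatives of the results of named genes, 2656 kept their side of the threshold and direction, 92 lost a call, 38 gained one and 0 reversed. Over 1496 of gene lists these were 1380, 89, 26 and 1. Most of these results had not passed in the main test and could not lose a call. The totals therefore do not show how stable the calls were. Ciz1 kept its calls for genotype, males and females in every alternative and with each array left out, as did 1110008P14Rik except in males with the 6 male arrays alone. Without moderation the calls of Ces3b and Opalin for genotype, Rhoj and Apold1 in males, Sdf2l1 and Opalin in females and AA536875 by sex were lost. Over all rows Opalin and Hrk lost theirs for genotype, Apold1 in males, Sdf2l1 in females, and Nnt and AA536875 by sex, and without sex in the model Ces3b, Opalin and Hrk lost theirs. Opalin lost its call for genotype under median centring (adjusted p = 0.0574) and Nnt by sex under quantile normalization (0.0565). With the 6 arrays of that sex alone Opalin in females (0.175) and Nnt (0.18), Apold1 (0.566) and 1110008P14Rik (0.0526) in males lost theirs. No list that passed changed the sign of its median under quantile normalization or median centring.

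The count for genotype (5) became 2 without sex in the model, 18 with an intensity trend, 3 without moderation, 14 over genes above the median brightness (fewer genes tested), 12 by unadjusted p with 1.5-fold and 3 with the choroid plexus level as a covariate, where Opalin and Hrk were lost, and ranged from 3 to 8 with an array left out (3 without WT_male replicate 3, where Xist stood out; 8 without WT_female replicate 3). The 18 included the 5, and Mal, Nr4a2, Ndufs4, Rhoj, Sdf2l1, Mpp4, Creld2, Gng3 and Apold1 were among the others. For males (5) it became 3 without moderation, 8 over all rows, 2 with the 6 male arrays alone (fewer samples) and 28 by unadjusted p, and 2 to 4 with an array left out. For females (5) it became 26 with a trend, 16 over bright genes, 9 over genes above a log2 mean of 5 and 53 by unadjusted p, and 3 to 7 with an array left out. For the interaction (0) it became 2 with a trend, 2 over bright genes, 1 above a log2 mean of 5 and 112 by unadjusted p, and 0 to 1 with an array left out. For sex (8) it became 15 with a trend, 13 over all rows and 13 over bright genes, and 6 to 8 with an array left out. With the choroid plexus covariate 4 of the 5 remained in males (without Apold1), 4 of the 5 in females (without Sdf2l1) and 7 of the 8 by sex (without Nnt), and no difference of these genes changed sign.

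Lists called with the preset correlation numbered 6 for genotype, 8 in males, 5 in females and 4 for the interaction. With an estimated correlation each became 0. By fry they became 0, 0, 3 and 1. In males 5 were called over bright genes. With an array left out the counts ranged from 5 to 7 for genotype, 4 to 8 in males, 3 to 6 in females and 4 to 8 for the interaction. The choroid plexus markers in males turned direction without WT_male replicate 1 (adjusted p = 0.92), the male with the highest Ttr; without the other arrays the adjusted p was as low as 1.75e-05. Without Xist the escape list kept its calls in males (adjusted p = 0.0291; range over all alternatives 0.00397 to 0.476), in females (0.0266) and for the interaction (0.000135). Where no cause is named, the cause was not tested. Dim genes, such as Ces3b, carry little signal over background.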

Other observations

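The listing of genes set apart in KO_female and the counts by the intensity trend were looked at after the result was seen, and the genes below were chosen from them.

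Trank1 was lower in all 3 KO_female arrays, at 8.46 to 9.03, than in the other 9 arrays, at 9.48 to 9.89, but passed neither in females (adjusted p = 0.085) nor for the difference between the sexes (adjusted p = 0.719). In females it passed with an intensity trend (adjusted p = 0.00522), over genes above the median brightness (0.0145) and without KO_female replicate 2 (0.0427). Manf, an ER stress protein, stood at 7.80 ± 0.02 (SD, n = 3) in KO_female and at 7.35 on average elsewhere. Zbtb16, a zinc finger transcription factor, was lower in all 3 WT_male arrays, at 7.63 ± 0.02 (SD, n = 3), than in the others, at 8.34 on average, and 18 of 100 random sets of 3 arrays had as many genes set apart as WT_male. With an intensity trend the genes past the threshold for genotype included Ccl3, a chemokine (0.56; adjusted p = 0.0273), Psat1, an enzyme of serine synthesis (-0.34; adjusted p = 0.0189), Mif (0.25; adjusted p = 0.0341) and Unc13a, which primes synaptic vesicles (0.19; adjusted p = 0.0341).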
